A study of Mus musculus with 8 samples.

How the data were processed

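Polyadenylated RNA of the suprachiasmatic nucleus (SCN) of C57/BL6 mice was measured in 8 libraries, 1 every 6 h over 2 days in darkness. Per the labels' protocols, equal amounts of RNA from 3 mice were pooled for each time and a strand-preserving polyA kit was used. The labels state no replicates, so each circadian time was taken as a group of 2 libraries collected 24 h apart. Replicate 1 is the library of the first cycle (22 to 40 h) and replicate 2 that of the second (46 to 64 h). This numbering is own and does not pair samples. Every p-value therefore measures spread between pooled libraries, not between mice. The times come from the library titles, and hours past 24 were reduced to circadian time (CT). The labels also give a start of collection at CT18, while the first library is titled CT22.

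Per the submitters' processing notes, reads were aligned with STAR 2.3.0e to mm9. The deposited tables hold whole-number read counts per gene (sense and antisense), intron, exon and splice junction. The counting tool, its strand setting and the step that equalised depth are not given in the sources used here. Column totals within each of the sense gene, antisense gene, intron and exon tables were nearly equal between libraries, so depth was equalised table by table before deposit. Differences between libraries in the ratio of antisense to sense reads, or of intron to gene reads, were thereby lost. The authors' tables also hold an adjusted p-value and a q-value per row from a JTK rhythm test with a 24-h period, per the file headers. A peak time in hours (lag) from the same JTK test is given in the authors' tables, per the file headers. The antisense exon and intron tables were not used here. No column of a used table was left without a sample.

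The tables hold 20741 genes, 15290 genes on the opposite strand, 176269 introns, 292239 exons and 229190 junctions. Genes are named by symbol, with coordinates on mm9. Of the sense gene IDs, 19628 were found in the table of gene names, as were 14609 of the antisense ones. Intron counts were summed per gene over 137093 introns that bore 1 gene symbol and did not overlap within that gene. For exon usage, 177943 exons were kept by the same criteria.

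Counts were tested with edgeR 4.0.16 (quasi-likelihood F test) in R 4.3.3, with TMM scaling and Benjamini-Hochberg adjustment at 0.05. Features needed at least 10 reads in at least 2 libraries. The model had a day-night term (CT4 and CT10 against CT16 and CT22) and a dusk-dawn term (CT10 and CT16 against CT22 and CT4). Together these are a 24-h cosine of free phase, tested with 2 degrees of freedom, which left 5 residual degrees of freedom. Peak-to-trough ratio and phase were computed from both coefficients, with standard errors by the delta method. Further tests were a 12-h term (CT4 and CT16 against CT10 and CT22) and a term for the second cycle against the first. At 6-h sampling a 12-h rhythm is seen in 1 phase only. Antisense, intron and junction counts used the effective library sizes of the sense genes. Exon usage was tested with the diffSpliceDGE function of edgeR (Simes test per gene) in genes with at least 2 exons. The common biological coefficient of variation was 0.143 for genes, 0.431 for antisense, 0.189 for introns and 0.346 for junctions. CPM values are counts scaled by effective library size (edgeR CPM), given as mean ± SD of 2 libraries.

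A set of 15 pathway and SCN lists and 15 lists of cell-type markers, 423 symbols in all, was tested with camera of limma 3.58.1 at a preset correlation of 0.01. Of these symbols, 417 matched the gene table and 4 were dropped as second names of the same gene. The pathway lists were core clock, clock modifiers, SCN peptides and receptors, SCN identity, immediate-early genes, heat shock, cold-inducible genes, endoplasmic reticulum (ER) folding, cholesterol synthesis, glucocorticoid-responsive genes, oxidative phosphorylation, glycolysis, ion channels of firing, GABA signalling and cAMP signalling. The marker lists were oligodendrocyte, oligodendrocyte precursor, astrocyte, microglia, endothelial, mural, meninges, ependyma, tanycyte, choroid plexus, magnocellular, arcuate, telencephalic and thalamic neuron, pituitary and blood. List p-values were adjusted over 60 tests (30 lists, both axes) and computed again with an estimated correlation. The score of a list in a library is the mean over members of log2 CPM (prior count 2) minus the mean of that member. Counts of members were given over all genes and adjusted over the list alone. For 1 list a member count is not reported here.

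Named genes followed a rule: each tested core clock gene; up to 10 other rhythmic genes with the largest peak-to-trough ratio, a mean CPM of at least 5, and the same highest and lowest circadian time in both cycles; up to 3 members of each other list with the lowest p; and the 5 features with the lowest p past the threshold among introns, junctions, antisense genes and exon usage. Genes named outside the rule are said to have been chosen after their values were seen. A test with 2 degrees of freedom has no sign, so a rhythm counts as reversed when its phase moved by more than 6 h. The comparisons, lists, naming rule and a first set of alternatives were fixed before the data were examined.

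That first set was DESeq2 size factors, no scaling, no filter, a mean of at least 50 reads, DESeq2 1.42.0 (likelihood ratio or Wald test), leaving out each library in turn, the cycle as a replicate block, a linear time trend, TMM on the features themselves, and a gene-level F test for exons. Alternatives chosen after seeing the data were an oligodendrocyte score, the 12-h contrast or the number of genes without a read as a further term, and leaving out both the 22-h and the 28-h library. Libraries were relabeled 100 times, the real labels included (40 times for junctions and 30 for exon usage), drawn from the distinct assignments to circadian times.

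The 24-h, 12-h, cycle, list and exon usage tests were run on simulated data drawn from the means of these genes. The test of a changed rhythm between cycles, the gene-level F test for exons and the test of exons marked as new were not. Rhythms were simulated in 200 of 14966 genes, drawn from those with a mean of at least 50 reads. Of these, 16% at a ratio of 1.5 and 69% at a ratio of 2 were called, and 11 flat genes were called with them (11.5% of calls). The median phase error at a ratio of 2 was 0.534 h. For genes changed 2-fold, again with a mean of at least 50 reads, 91% were called by the 12-h test and 94% by the cycle test. At a ratio of 2, the share called was 31.1% for introns, 0% for antisense genes and 0% for junctions. These were drawn from all tested features without that floor of reads, so the shares cannot be compared directly with those of genes. Exon usage changes of 2-fold, in exons with a mean of at least 50 reads, were called in 25.5% of genes. Camera called a raised list (adjusted p = 1.1e-40) and 0 of 20 random lists. Simulated genes were drawn independently of each other, so this cannot show how camera treats lists of correlated genes. In the other relabelings of the real libraries a median of 18 list tests passed, against 19 with the real labels. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.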

Results

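RNA of the mouse SCN, the pacemaker of the hypothalamus, was sequenced every 6 h over 2 days in constant darkness. The 8 libraries, each a pool of 3 mice, fell on 4 circadian times with 2 libraries each: CT4 and CT10 in the subjective day, CT16 and CT22 in the subjective night. Each library held 11123610 to 11131890 reads on the sense strand of genes and 149603 to 149800 on the opposite strand. Intron reads numbered 4196931 to 4199146 per library, exon reads 25232810 to 25232813 and junction reads 3196136 to 3437120. The title of the series names circadian control of SCN genes as its subject, and the comparisons below ask which transcripts followed circadian time.

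Of 20 tested clock genes, 5 followed a 24-h rhythm in darkness by edgeR. The protein products of the clock genes form the transcriptional feedback loop of the pacemaker. Nr1d1, Per1, Dbp, Gm129 (Ciart) and Per2 had fitted peaks in the subjective day, listed here by fitted time. Dbp peaked at CT7.46 ± 0.363 h (SE) and Gm129 at CT8.39 ± 0.532. The order was not tested, and the SEs of Gm129 and Per2 overlapped. Nr1d1 (ENSMUSG00000020889, mm9 chromosome 11, 98629198-98636708) peaked at CT4.89 ± 0.486 h (SE), with 98.8 ± 15 CPM (SD, n = 2) at CT4 and 47.4 ± 2.34 at CT16. Per1 (ENSMUSG00000020893, chromosome 11, 68908711-68923550) peaked at CT6.79 ± 0.443, with 86.2 ± 16.2 CPM at CT10 and 41.8 ± 0.484 at CT16. Dbp (ENSMUSG00000059824, chromosome 7, 52960391-52965574) had 86.4 ± 9.18 CPM at CT10 and 35.4 ± 4.28 at CT16. Gm129 (ENSMUSG00000038550, chromosome 3, 95682362-95686230) had 20.9 ± 0.155 CPM at CT10 and 7.70 ± 0.491 at CT22. Per2 (ENSMUSG00000055866, chromosome 1, 93312358-93355922) peaked at CT8.80 ± 0.465, with 101 ± 18.6 CPM at CT10 and 43.6 ± 4.69 at CT22. Their log2 peak-to-trough ratios were 1.08 ± 0.14 (SE) for Nr1d1, 1.29 ± 0.15 for Per1, 1.64 ± 0.16 for Dbp, 1.60 ± 0.22 for Gm129 and 1.27 ± 0.16 for Per2. The adjusted p of edgeR was 0.00834, 0.00323, 0.000317, 0.0157 and 0.00495 in the same order. Without 1 library, Nr1d1 lost its call in the absence of CT4 replicate 2 (adjusted p = 0.0820) or CT16 replicate 2 (0.0983), Gm129 in the absence of CT10 replicate 1 (0.117) or CT10 replicate 2 (0.137), and Per2 in the absence of CT10 replicate 2 (0.121). Per1 and Dbp kept theirs in all 8 leave-outs. With all libraries, edgeR did not call the other 15 clock genes. Arntl, the positive partner of the loop, had a fitted peak at CT21.4 and a ratio of 1.58 (adjusted p = 0.319). Rora had a ratio of 2.07 (adjusted p = 0.0860) and passed by DESeq2. Cry1 had a ratio of 1.35 (adjusted p = 0.516).

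**Figure D1:**
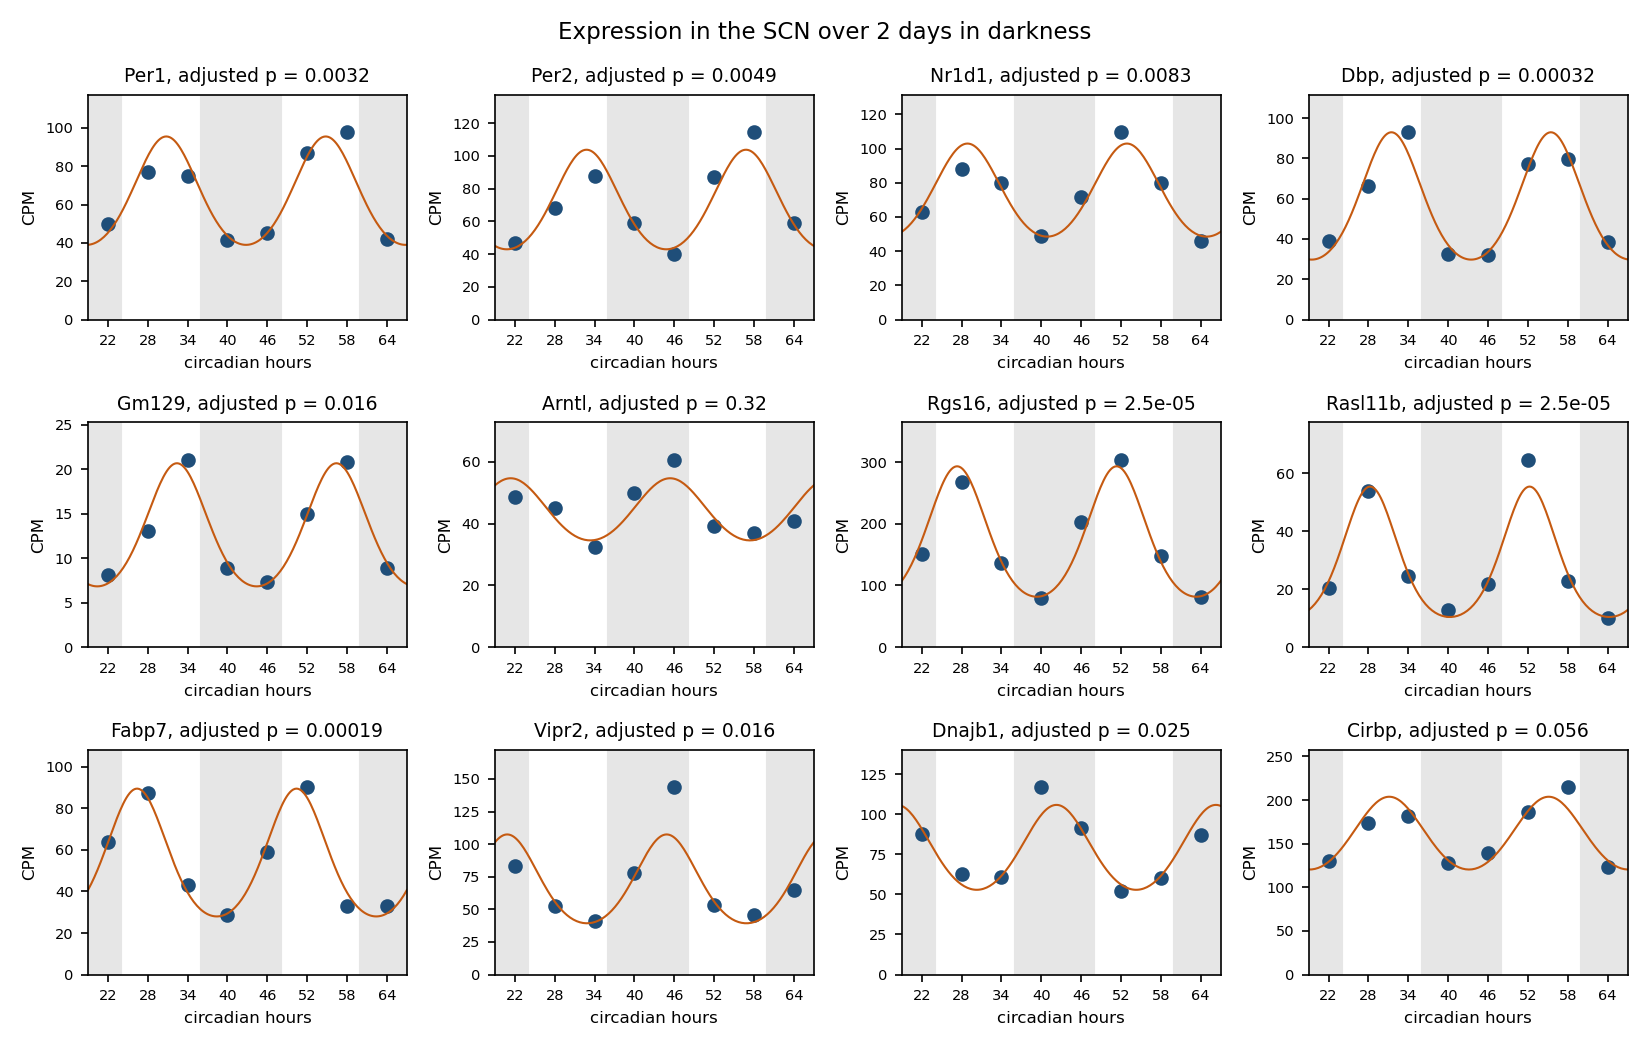
CPM of 12 genes in each of the 8 libraries (points) against hours of collection, with the fitted 24-h curve (line) and the subjective night shaded grey. Per1 and Dbp were lowest at CT16 or CT22 in both cycles, and Rgs16 fell from 286 CPM at CT4 to 81.1 at CT16 on average.

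Rgs16, Rasl11b, Dusp4 and Fabp7 peaked between CT2.39 and CT4.59, and Vipr2 in the late night. Rgs16, which shortens G-protein signals, had 286 ± 25.5 CPM (SD, n = 2) at CT4 and 81.1 ± 1.13 at CT16 (ENSMUSG00000026475, mm9 chromosome 1, 155587463-155592781). Its log2 peak-to-trough ratio was 1.84 ± 0.14 (SE) with a peak at CT3.34 ± 0.284 h. Rasl11b, a Ras-like GTPase, had a log2 ratio of 2.42 ± 0.19 with a peak at CT4.26 ± 0.299 (ENSMUSG00000049907, chromosome 5, 74591292-74595640). Dusp4, a phosphatase of MAP kinases, had a log2 ratio of 2.66 ± 0.29 with a peak at CT4.59 ± 0.420 (ENSMUSG00000031530, chromosome 8, 35870264-35883097). Fabp7, a lipid-binding protein of astroglia, had a log2 ratio of 1.68 ± 0.15 with a peak at CT2.39 ± 0.346 (ENSMUSG00000019874, chromosome 10, 57504667-57508288), while the astrocyte markers as a list showed no day-night (adjusted p = 0.524) or dusk-dawn difference (adjusted p = 0.435). The receptor of vasoactive intestinal peptide, Vipr2, peaked at CT20.9 ± 0.541, with 113 ± 42.5 CPM at CT22 and 43.7 ± 3.36 at CT10 (ENSMUSG00000011171, chromosome 12, 117316180-117384946). The adjusted p of edgeR was 2.5e-05 for Rgs16, 2.5e-05 for Rasl11b, 0.00144 for Dusp4, 0.000188 for Fabp7 and 0.0157 for Vipr2. The first 4 of these passed in all 8 leave-outs, and Vipr2 was lost without CT10 replicate 1, CT4 replicate 2 or CT10 replicate 2 (adjusted p from 0.0538 to 0.0838).

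In all, 17 of 15217 genes were rhythmic by edgeR, against 98 by DESeq2, 362 by edgeR without a filter (1 of them below the filter used here) and 1308 at an unadjusted p under 0.05. The ratios of the 17 genes ran from 1.83 to 10.7, and 8 peaked between CT4 and CT10, 0 between CT10 and CT16, 5 between CT16 and CT22 and 4 between CT22 and CT4. The genes not yet named were Tmem51 (peak CT23.6, ratio 3.33), B3gat2 (CT23.2, 1.83), the heat shock genes Dnajb1 (CT18.3, 2.00) and Hspa1b (CT17.5, 10.7), the RNA-binding gene Sfpq (CT17.5, 1.86), Prex2 (CT18.6, 1.84) and Hmgb3 (CT5.99, 1.96), of which Prex2 and Hmgb3 were chosen after their values were seen. Hspa1b shares near-identical sequence with Hspa1a and is uncertain. It also had few reads: 190 at CT16 replicate 2, 79 at CT16 replicate 1, 66 at CT22 replicate 1 and at most 27 elsewhere. The adjusted p of these genes ran from 0.0212 (Prex2) to 0.0444 (Hspa1b). Tmem51 and B3gat2 passed only without CT22 replicate 1, CT4 replicate 1 or CT16 replicate 1, with an adjusted p of 0.0595 to 0.221 and 0.0633 to 0.192 without each other library. Dnajb1 was lost without CT10 replicate 1, CT4 replicate 2 or CT10 replicate 2 (0.0838 to 0.150). Sfpq passed only without CT22 replicate 1 or CT22 replicate 2 (else 0.0538 to 0.20), Hspa1b only without CT16 replicate 1 or CT22 replicate 2 (else 0.0691 to 0.418), Hmgb3 only without CT4 replicate 1 or CT22 replicate 2 (else 0.0638 to 0.248), and Prex2 only without CT22 replicate 1, CT16 replicate 1 or CT22 replicate 2 (else 0.0595 to 0.109). The count was 7 without CT10 replicate 2, 8 without CT10 replicate 1 and 43 without CT16 replicate 1. As many calls arose in 6 of 100 relabelings of the libraries, the real labels included and 6 genes (Rgs16, Rasl11b, Dusp4, Fabp7, Per1 and Dbp) passed in all leave-outs. With the oligodendrocyte score as a term, chosen after the data were seen, Tmem51 (0.0706), B3gat2 (0.0554) and Hspa1b (0.0615) were lost, and Hspa1b also without scaling (0.0734).

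**Figure D2:**
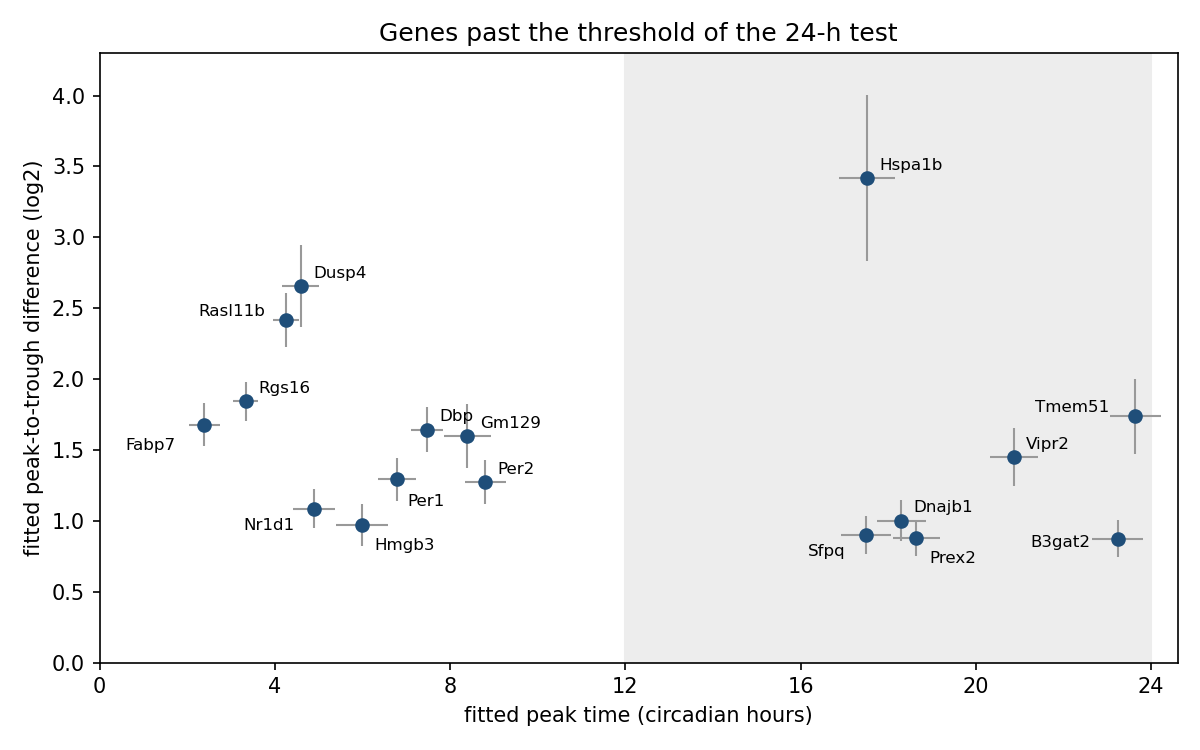
Peak time (CT, in hours) against log2 peak-to-trough ratio of the 17 rhythmic genes, with standard errors as bars. The ratio ran from 1.83 (B3gat2) to 10.7 (Hspa1b) on the linear scale, and 0 genes peaked between CT10 and CT16. Hspa1b had 190 reads at CT16 replicate 2 and at most 79 in any other library.

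Subjective day was compared with subjective night with the dusk-dawn axis in the model. By day, clock genes (Nr1d1, Per1, Per2, Dbp, Gm129) and the signalling genes Rgs16, Rasl11b and Dusp4 were higher, as was Cirbp, whose RNA-binding protein is induced by mild cold. Dbp was 2.22-fold, Per1 1.88-fold, Per2 1.74-fold and Cirbp 1.45-fold higher by day, and Dnajb1 (0.617-fold), Vipr2 (0.534-fold) and Sfpq (0.666-fold) were lower. By edgeR 11 genes were higher and 5 lower by day, 16 in all, against 56 by DESeq2 and 1174 at an unadjusted p under 0.05. Hmgb3 and Armcx5 (higher) and Prex2 and Gm12940 (lower), chosen after their values were seen, complete the 16. Gm12940 overlaps Sfpq on chromosome 4. Rasl11b, Rgs16, Per1 and Dbp passed in all leave-outs (adjusted p from edgeR with all libraries of 0.000454, 0.00373, 0.00140 and 0.000321). Dusp4, Per2 and Prex2 were lost without CT10 replicate 2 (0.0531 each), Nr1d1 without CT4, CT10 or CT16 replicate 2 (0.0537 to 0.0703), Gm129 without CT10 replicate 1, CT10 replicate 2 or CT16 replicate 2 (0.0589 to 0.0871), and Dnajb1 without CT10 replicate 1, CT4 replicate 2 or CT10 replicate 2 (0.0549 to 0.0881). Cirbp passed only without CT4 replicate 1, CT10 replicate 1 or CT22 replicate 2 (else 0.0547 to 0.119), Vipr2 only without CT22 replicate 1, CT22 replicate 2 or CT16 replicate 2 (else 0.0531 to 0.106), Sfpq only without CT22 replicate 1, CT22 replicate 2 or CT4 replicate 2 (else 0.0501 to 0.119), and Hmgb3 only without CT22 replicate 1, CT4 replicate 1 or CT22 replicate 2 (else 0.0549 to 0.119). Armcx5 passed only without CT10 replicate 1 or CT22 replicate 2 (else 0.0501 to 0.224) and Gm12940 only without CT22 replicate 2 or CT4 replicate 2 (else 0.0885 to 0.199). The count was 4 without CT10 replicate 2, 10 without CT10 replicate 1 and 28 without CT22 replicate 2.

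Around dusk, Rgs16, Fabp7 and Rasl11b were lower than around dawn. Rgs16 was 0.477-fold (adjusted p = 0.000142 by edgeR), Fabp7 0.464-fold (0.000182) and Rasl11b 0.459-fold (0.00177) at dusk relative to dawn. These 3 genes passed in all 8 leave-outs, and 0 genes were higher at dusk. DESeq2 called 34 genes on this axis, and 1193 had an unadjusted p under 0.05. The count was 60 without CT16 replicate 1, 6 without CT22 replicate 1 and 5 without CT22 replicate 2.

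As lists, protein-folding genes were lower by day and cold-inducible RNA-binding genes higher, the latter in 2 of 3 genes. The 19 tested heat shock genes, which encode chaperones such as Dnajb1, were all lower by day, with a median of 0.790-fold. Dnajb1 had 57.5 ± 7.38 CPM (SD, n = 2) at CT4 and 102 ± 20.9 at CT16, and Chordc1 was 0.589-fold by day. Of the 3 cold-inducible genes, Cirbp had 180 ± 9.05 CPM at CT4, 198 ± 23.4 at CT10 and 126 ± 3.21 at CT16. Rbm3 had 194 ± 14.0 at CT10 but 115 ± 7.65 at CT4, near its 102 ± 4.98 at CT22 and 109 ± 1.37 at CT16. Srsf5 was 0.901-fold by day. On the day-night axis by edgeR, Cirbp passed (adjusted p = 0.0171), while Rbm3 (0.158) and Srsf5 (0.750) did not. Of the ER folding genes, 15 were lower by day, among them Sdf2l1 (0.467-fold) and Creld2 (0.725-fold). By camera the adjusted p was 1.7e-27 for heat shock, 0.000259 for cold-inducible and 4.9e-06 for ER folding genes. With an estimated correlation the adjusted p was 0.132, 0.264 and 0.332, so these list calls rest on the preset correlation. Over all genes 2, 0 and 0 members were rhythmic by edgeR, and adjusted over the list alone 13, 2 and 7. Cirbp passed the 24-h test by DESeq2, and by edgeR with the 12-h contrast as a term, chosen after the data were seen. On the dusk-dawn axis ER folding genes were higher at dusk (adjusted p = 0.0153, and 0.714 with an estimated correlation), a call lost without CT22 replicate 1 (0.142), CT16 replicate 1 (0.221), CT22 replicate 2 (0.0837) or CT16 replicate 2 (0.0611). On that axis heat shock and cold-inducible genes had adjusted p of 0.473 each.

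**Figure D3:**
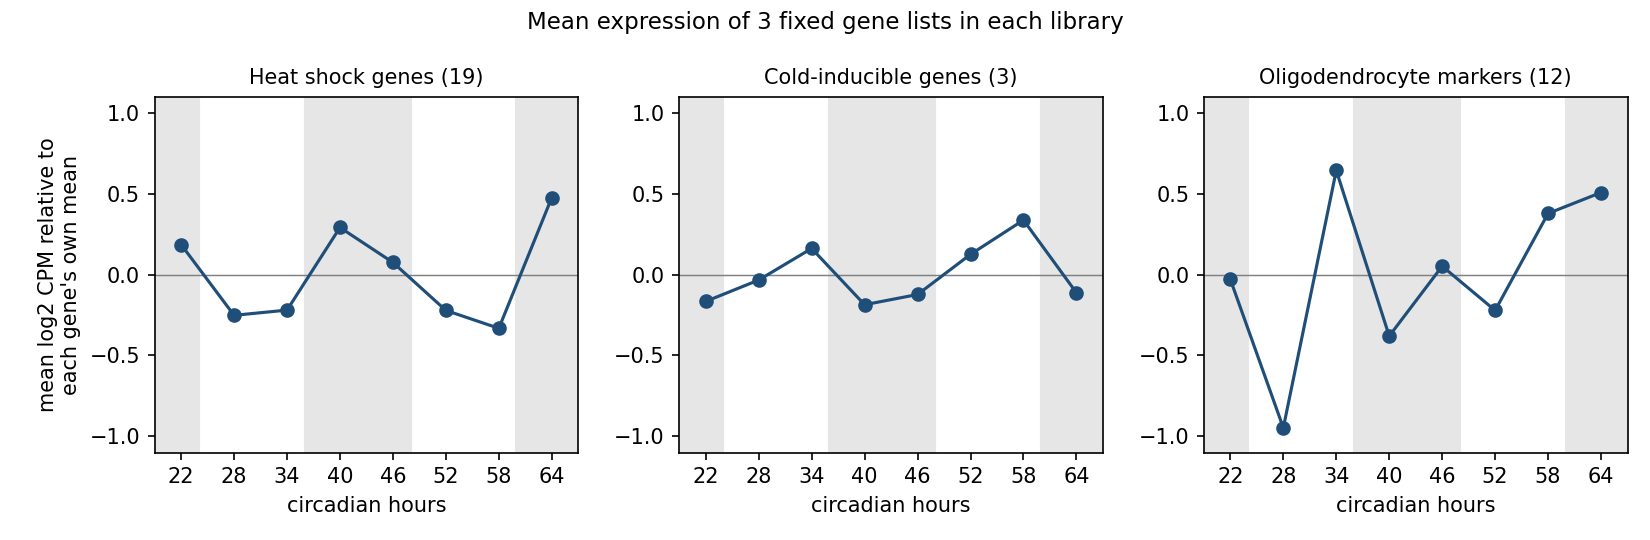
Mean log2 CPM of heat shock (19 genes), cold-inducible (3) and oligodendrocyte (12) lists relative to their own means in the 8 libraries, against hours of collection. The heat shock score was highest at CT16 replicate 2 (0.475) and lowest at CT10 replicate 2 (-0.332), and the oligodendrocyte score ran from -0.947 (CT4 replicate 1) to 0.643 (CT10 replicate 1).

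The core clock list was higher by day in 15 of 20 members, with a median of 1.18-fold (adjusted p = 1.2e-16 by camera, and 0.132 with an estimated correlation). Over all genes 5 members were rhythmic by edgeR, while Rora also passed by DESeq2. Adjusted over the list alone 14 were, including Cry1, Cry2, Per3, Tef, Nr1d2, Rora, Rorb, Npas2 and Arntl. The 5 became 3 without CT10 replicate 2. Lists of energy metabolism were slightly higher by day as a whole. This held for 17 of 18 glycolysis genes (median 1.06-fold, adjusted p = 0.00251 by camera, and 0.781 with an estimated correlation). It also held for 19 of 22 oxidative phosphorylation genes (median 1.04-fold, adjusted p = 0.0396, and 0.839 with an estimated correlation). With the oligodendrocyte score as a term, chosen after the data were seen, oxidative phosphorylation was lost (0.0520). Glycolysis was lost without CT4 replicate 1 (0.0603) or CT16 replicate 2 (0.196), and oxidative phosphorylation without CT4 replicate 1 (0.244), CT10 replicate 1 (0.279) or CT16 replicate 2 (0.381). Mural-cell markers were higher by day (median 1.13-fold, adjusted p = 0.0396, and 0.714 with an estimated correlation) but not without CT22 replicate 1 (0.244), CT10 replicate 1 (0.157), CT16 replicate 1 (0.199) or CT4 replicate 2 (0.392). Arcuate markers were higher by day in 6 of 6 (median 1.61-fold, adjusted p = 0.0250, and 0.668 with an estimated correlation). That call was lost without CT10 replicate 1 (0.587), which held 582 reads of Pomc (chosen after its values were seen) against at most 129 elsewhere, or without CT4 replicate 1 (0.0577), CT16 replicate 1 (0.199), CT22 replicate 2 (0.0540) or CT16 replicate 2 (0.0820). Of the glycolysis, oxidative phosphorylation, mural and arcuate lists 0 members were rhythmic by edgeR over all genes, and 0 adjusted over the list alone. On the dusk-dawn axis the adjusted p was 0.992 for the core clock, 0.104 for glycolysis, 0.123 for oxidative phosphorylation, 0.487 for mural and 0.401 for arcuate markers.

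Along the dusk-dawn axis, 5 lists of SCN and neuronal genes were lower at dusk. Among SCN peptides and receptors 11 of 17 were lower at dusk, such as Vipr2 (0.717-fold) and Prokr2 (0.728-fold), as were 10 of 16 SCN identity genes and 17 of 22 immediate-early genes, among them Fosl2 (0.577-fold), Sik1 (0.685-fold) and Btg2 (0.732-fold). By edgeR none of these genes but Vipr2 and Rgs16 was rhythmic over all genes, and adjusted over the list alone 5 were in each of the 3 lists. That 24-h test covers both axes. On the dusk-dawn axis alone, Rgs16 passed (adjusted p = 0.000142 by edgeR). Vipr2 (0.425), Prokr2 (0.452), Fosl2 (0.272), Sik1 (0.271) and Btg2 (0.403) did not. Ion channels of firing (18 of 25 lower) and GABA signalling genes (19 of 24 lower) were also lower at dusk, with 1 and 0 members adjusted over the list alone. By camera the adjusted p was 0.00395 for peptides and receptors, 0.000259 for identity genes, 1.8e-05 for immediate-early genes, 0.0325 for ion channels and 0.0138 for GABA signalling. With an estimated correlation the adjusted p was 0.286, 0.286, 0.413, 0.714 and 0.825. Immediate-early genes were lost without CT22 replicate 1 (0.0553). Ion channels were lost without CT22 replicate 1 (0.119), CT4 replicate 1 (0.0777), CT10 replicate 1 (0.218), CT4 replicate 2 (0.0523) or CT16 replicate 2 (0.196), and GABA signalling without CT4 replicate 1 (0.313), CT10 replicate 1 (0.205) or CT16 replicate 2 (0.0884). With the oligodendrocyte score as a term, chosen after the data were seen, ion channels were lost (0.728) and GABA signalling changed direction (0.583). Between day and night the adjusted p of these 5 lists was 0.638, 0.0786, 0.992, 0.248 and 0.648.

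Markers of myelin-forming oligodendrocytes were higher at dusk in 12 of 12 genes, with a median of 1.51-fold. Mbp, the myelin basic protein gene, ranged from 16677 reads at CT4 replicate 1 to 56471 at CT10 replicate 1. Glucocorticoid-responsive genes, which adrenal steroids induce, were higher at dusk in 14 of 14 (median 1.27-fold), among them Sgk1 (1.73-fold), Tsc22d3 (1.47-fold) and Plin4 (1.74-fold). Markers of oligodendrocyte precursors (6 of 6), microglia (9 of 10) and meninges (8 of 9) were also higher at dusk. By camera the adjusted p was 3.0e-11 for oligodendrocytes, 7.0e-07 for glucocorticoid-responsive genes, 0.0188 for precursors, 0.00194 for microglia and 0.000389 for meninges. With an estimated correlation the adjusted p was 0.478, 0.668, 0.332, 0.668 and 0.714. Over all genes 0 members of these lists were rhythmic by edgeR, and adjusted over the list alone 8, 5, 1, 0 and 0. With the oligodendrocyte score as a term, chosen after the data were seen, the adjusted p was 0.443 for glucocorticoid-responsive genes and 0.586 for microglia, and meninges became lower at dusk (0.0141). Precursors were lost without CT22 replicate 2 (0.0542) and meninges without CT4 replicate 1 (0.668). Between day and night the adjusted p of these 5 lists was 0.473, 0.422, 0.473, 0.401 and 0.401.

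The remaining lists passed on neither axis, and their rhythmic genes were counted by edgeR. Clock modifiers (adjusted p = 0.422 for day-night and 0.565 for dusk-dawn) held 1 rhythmic gene, Sfpq, and 3 adjusted over the list alone (Sfpq, Fbxl21 and Id2). Cholesterol synthesis (0.945 and 0.584) held 0, and cAMP signalling (0.654 and 0.190) held 0 over all genes and 4 adjusted over the list alone, Creb3l1 among them. The astrocyte list, given above with Fabp7, held 0. Endothelial (0.676 and 0.565), ependyma (0.832 and 0.822), tanycyte (0.945 and 0.524), choroid plexus (0.681 and 0.575), magnocellular (0.908 and 0.473), telencephalic and thalamic neuron (0.565 and 0.143 by camera), pituitary (0.327 and 0.143) and blood markers (0.473 and 0.161) held 0 rhythmic genes over all genes. Adjusted over the list alone, choroid plexus held 1 (Ttr), pituitary 2 (Gh and Prl), and the endothelial, ependyma, magnocellular, telencephalic and thalamic neuron and blood lists 0. The median and the test differed in sign in 6 of the 60 list tests, 0 of them past the threshold, and 19 of 60 passed in all.

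The 12-h term and the cycle term addressed shorter rhythms and change from the first to the second day in darkness. By edgeR 0 genes passed for the 12-h term, against 8 by DESeq2 and 1137 at an unadjusted p under 0.05, where 761 would arise with no effect. The lowest adjusted p was 0.361. The count was 33 without CT4 replicate 2, 4 without CT22 replicate 2, 1 without CT4 replicate 1 and 1 without CT10 replicate 2. For example Rgs16 had an adjusted p of 0.917 and Rasl11b of 0.727 for the 12-h term. By edgeR 0 genes differed between cycles, against 0 by DESeq2 and 543 at an unadjusted p under 0.05 (lowest adjusted p 0.999). The count was 2 without CT16 replicate 1, 1 without CT10 replicate 1 and 1 without CT16 replicate 2. A change of the 24-h rhythm between cycles was found for 0 genes by edgeR (394 at an unadjusted p under 0.05, lowest adjusted p 0.0534, not run with DESeq2).

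Introns, whose reads come largely from unspliced RNA, were rhythmic in the SCN peptide genes Avp and Prok2. Avp, the vasopressin gene (ENSMUSG00000037727, mm9 chromosome 2, 130406333-130408304), had 8.76 ± 1.35 intron CPM (SD, n = 2) at CT4 and 0.945 ± 0.433 at CT16, a ratio of 10.5 with a peak at CT2.96. Prok2, prokineticin (ENSMUSG00000030069, chromosome 6, 99661178-99676402), had 5.34 ± 2.23 at CT4 and 0.450 ± 0.249 at CT16, a ratio of 14.7 with a peak at CT3.15. Rgs16 introns had a ratio of 5.43 (CT2.94), Dbp introns 2.99 (CT6.80) and Nr1d1 introns 2.87 (CT3.46). The adjusted p of edgeR was 0.000146 for Rgs16, 0.000156 for Dbp, 0.00188 for Avp, 0.00466 for Nr1d1 and 0.00494 for Prok2. The gene counts of Avp (ratio 2.55, adjusted p = 0.436) and Prok2 (3.48, 0.563) did not pass, and the difference between intron and gene was not tested. Without CT4 replicate 2, Avp (0.0550), Nr1d1 (0.0612) and Prok2 (0.195) were lost.

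In all, the introns of 36 of 13850 genes were rhythmic by edgeR, against 87 by DESeq2 and 1447 at an unadjusted p under 0.05. Of these, 18 peaked between CT22 and CT4, 10 between CT16 and CT22, 7 between CT4 and CT10 and 1 between CT10 and CT16, with ratios from 1.75 to 14.7. Among others, chosen after their values were seen, were the peptide gene Nms (CT21.9, ratio 5.07), the transcription factor Creb3l1 (CT4.94, 6.11), the chaperone Hsph1 (CT19.4, 1.81) and the myelin gene Mobp (CT13.4, 2.29). On the axes 7 were higher and 8 lower by day (1093 at an unadjusted p under 0.05, 48 by DESeq2), and 4 higher and 22 lower at dusk (1392 and 57). The count was 2 without CT4 replicate 2, 8 without CT10 replicate 2, 18 without CT16 replicate 2 and 22 without CT22 replicate 1 or CT4 replicate 1. The genes and introns of Dbp, Fabp7, Gm129, Nr1d1, Per1 and Rgs16 were both rhythmic. Their introns peaked a median of -0.530 h (SD 1.39 over 6 genes) relative to the gene, earlier in 5 of 6, with a larger ratio in 5 of 6. The difference ran from -3.42 h for Fabp7 to 0.497 h for Per1, with -0.008 h for Gm129. Single simulated genes had a median absolute phase error of 0.534 h at a ratio of 2. The error of a median over 6 such differences was not simulated, so whether introns came first cannot be told. Genes are not replicates, so no p is given. Introns of Per1 were lost without CT4 replicate 2 (adjusted p = 0.0550) or CT10 replicate 2 (0.0819), introns of Fabp7 without CT22 replicate 2 (0.172), CT4 replicate 2 (0.0550) or CT10 replicate 2 (0.178), and introns of Gm129 in each leave-out but that of CT16 replicate 1 (0.0612 to 0.271).

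**Figure D4:**
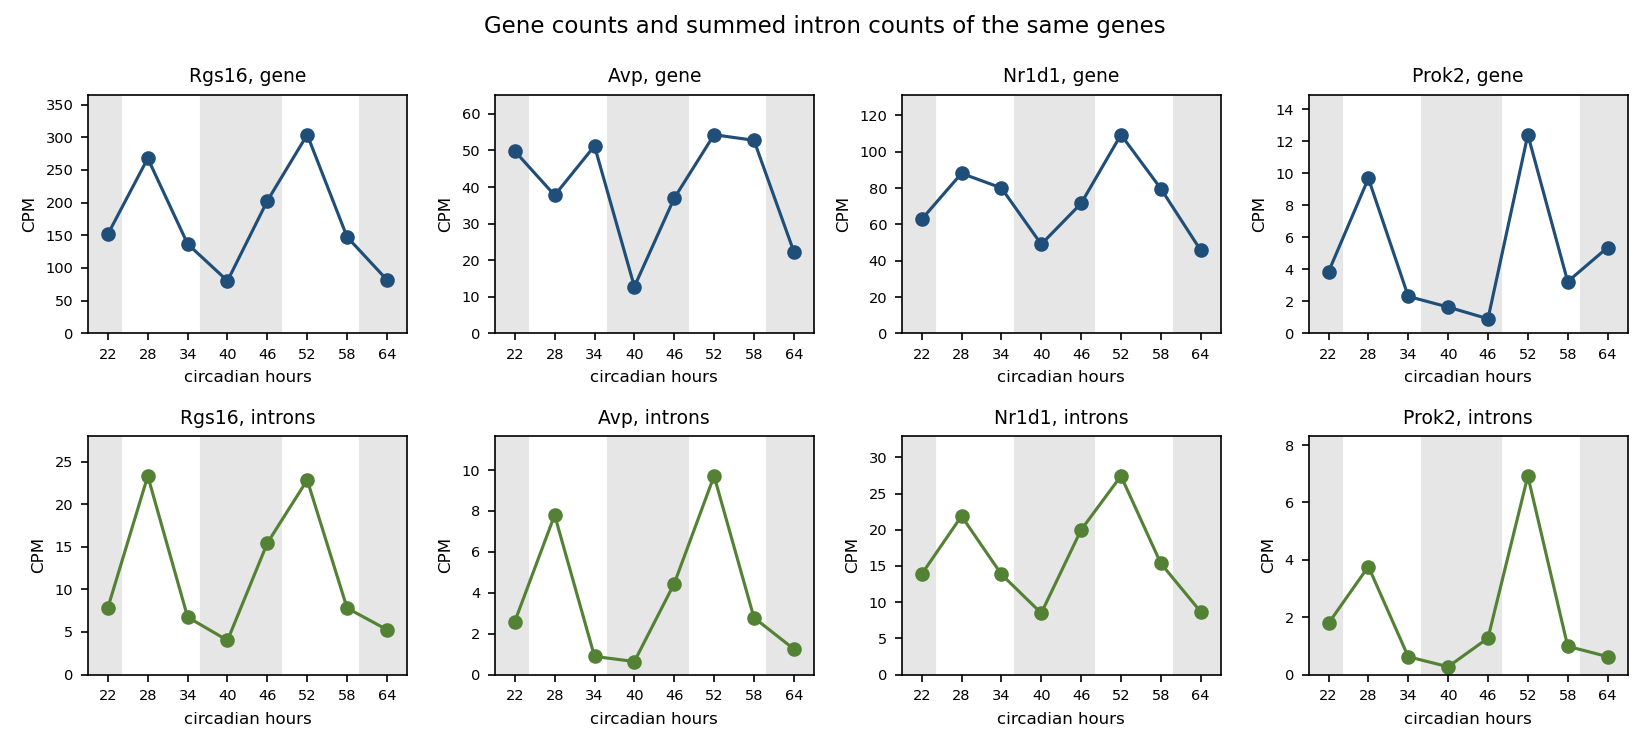
Gene and intron CPM of Rgs16, Avp, Nr1d1 and Prok2 in the 8 libraries against hours of collection. Avp introns stood at 8.76 CPM at CT4 and 0.945 at CT16 on average, and Prok2 introns at 5.34 and 0.450.

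Reads on the strand opposite to genes gave 0 rhythmic genes of 3693 by edgeR, with a lowest adjusted p of 0.881, against 0 by DESeq2. At an unadjusted p under 0.05 there were 128, fewer than would arise with no effect. Of simulated 2-fold antisense rhythms 0% were recovered, so such rhythms were not detectable here. The count was 1 without CT4 replicate 2.

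Single splice junctions of Dbp, Rbm3 and Srsf5 passed the 24-h test with all libraries. A junction of Dbp (mm9 chromosome 7, 52963842-52965034) had a ratio of 3.79 and a peak at CT7.80. A junction of the cold-inducible gene Rbm3 (chromosome X, 7721074-7721698) had a ratio of 4.31 and a peak at CT9.50, with 25.8 ± 1.40 CPM (SD, n = 2) at CT10 and 6.35 ± 0.123 at CT22. A junction of the splicing factor Srsf5 (chromosome 12, 82048853-82050081) had a ratio of 3.12 and a peak at CT4.55. Junction counts were not scaled to their gene, so a junction can follow its gene. The Dbp gene had a ratio of 3.12 and a peak at CT7.46, close to its junction. The genes of Rbm3 (1.91, CT9.67) and Srsf5 (1.22, CT21.8, adjusted p = 0.685 by edgeR) had smaller ratios than their junctions. Differences between junction and gene were not tested. Junctions of Pmch (chromosome 10, 87554632-87554884) and Chchd2 (chromosome 5, 130358451-130359804) rested on 1 library each: 175 reads at CT4 replicate 1 for Pmch and 217 at CT22 replicate 1 for Chchd2. Each of the 5 had an adjusted p of 0.0286 by edgeR. The Dbp junction was lost without CT22 replicate 1 (0.137), CT10 replicate 1 (0.169) or CT16 replicate 2 (0.137), and the Rbm3 junction without CT22 replicate 1 (0.0663), CT10 replicate 1 (0.288) or CT10 replicate 2 (0.354). The Srsf5 junction was lost without CT22 replicate 1 (0.0663), CT4 replicate 1 (0.246), CT4 replicate 2 (0.272) or CT16 replicate 2 (0.137). The Pmch junction was lost without CT22 replicate 1 (0.0663), CT4 replicate 1 (0.933), CT10 replicate 1 (0.0857) or CT16 replicate 2 (0.140) and by DESeq2 (0.266), and that of Chchd2 without CT4 replicate 1 (0.0802), CT10 replicate 1 (0.174) or CT4 replicate 2 (0.0746) and by DESeq2 (1.0). The Chchd2 junction fell below the filter without CT22 replicate 1 or CT16 replicate 2. With the 12-h contrast as a term, chosen after the data were seen, the Dbp, Rbm3 and Srsf5 junctions had an adjusted p of 0.0860 each, and 0 junctions passed by edgeR (4145 at an unadjusted p under 0.05, DESeq2 not run with this term). In all, 14 of 78212 junctions passed, against 27 by DESeq2 and 3910 at an unadjusted p under 0.05. The latter is about as many as would arise with no effect. Of the 14, 7 had at least 5 times as many reads in CT22 replicate 1 as in every other library. The count was 0 without CT22 replicate 1, 4 without CT4 replicate 1, 1 without CT10 replicate 1, 62 without CT16 replicate 1, 44 without CT22 replicate 2, 7 without CT4 replicate 2, 8 without CT10 replicate 2 and 1 without CT16 replicate 2.

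An exon of Rbm3 (mm9 chromosome X, 7715878-7718334) took a smaller share of the exon reads of the gene by day, 4.45% ± 2.73 (SD, n = 4), than at night, 13.2% ± 2.45 (adjusted p = 0.0129 by edgeR). Exons of Hnrnpu (chromosome 1, 180267084-180267936) and Wipi2 (chromosome 5, 143105467-143105786) also passed, with 430 and 76 reads at CT22 replicate 1 and at most 77 and 24 in any other library. The Rbm3 exon was lost without CT4 replicate 1 (0.0528), CT10 replicate 1 (0.260) or CT16 replicate 2 (0.138). The exons of Hnrnpu and Wipi2 passed only without CT16 replicate 1, CT22 replicate 2 or CT10 replicate 2 (else 0.172 to 1.0 and 0.260 to 1.0). Of 11574 genes with 104980 exons, these 3 passed for day-night (366 at an unadjusted p under 0.05, DESeq2 not run). For dusk-dawn 0 passed by edgeR (201 at an unadjusted p under 0.05, lowest adjusted p 0.231, DESeq2 not run), and 18 did by a gene-level F test. The unadjusted counts of 366 and 201 both lay below what would arise with no effect. For day-night that F test called 4 genes: Rbm3 (0.0492) and, chosen after their values were seen, Top1 (0.0309), Vldlr (0.0465) and Tnfrsf1b (0.0492), but not Hnrnpu (0.712) or Wipi2 (0.506). The day-night count was 1 without CT22 replicate 1 or CT4 replicate 2, 0 without CT4 replicate 1, CT10 replicate 1 or CT16 replicate 2, 16 without CT10 replicate 2, 27 without CT22 replicate 2 and 70 without CT16 replicate 1.

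The authors' own JTK test, per the file headers, gave 0 genes with a q under 0.05, with a lowest q of 0.823. The lowest JTK adjusted p was 0.000198, shared by 5 of 20741 genes. A q under 0.05 would have needed many more genes at or near that value, so the 0 says little. Of the 17 genes called here by edgeR, 10 had a JTK adjusted p under 0.05, Nr1d1 and Rasl11b with the lowest (0.000198). Unlike the adjusted p of edgeR, this JTK value is not adjusted over genes. The share of all genes under 0.05 by it was not counted. Both tests used the same libraries, so their calls and peak times are not independent. For 16 of the 17 the JTK peak time lay within 3 h of the phase fitted here, with a median difference of 1.51 h. The exception was Dnajb1, with a JTK peak at 8.5 h against CT18.3.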

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

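The rhythm test of these exons was chosen after the exon table was seen. The exon table holds 12760 exons that the authors marked as new, and 8698 of them had at least 10 reads in at least 2 libraries. They stood out as a signal in data that the comparisons above did not use, and the series has no control samples to set it against. They held 901288 to 931415 reads per library. By edgeR 0 of the 8698 were rhythmic, against 458 at an unadjusted p under 0.05, about as many as would arise with no effect. DESeq2 was not run on these exons. Exons in Meg3 (mm9 chromosome 12, 110796850-110797945), Rgs16 (chromosome 1, 155586732-155587642) and Hsph1 (chromosome 5, 150420962-150422120) had the lowest adjusted p, 0.208 each, as did an exon in Pcsk1n (chromosome X, 7499174-7499377) with 1209 reads at CT22 replicate 1 and at most 43 in any other library. No technical or biological explanation of these exons was tested.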

How the results depend on the processing

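The alternatives with an oligodendrocyte score, the 12-h contrast or the number of genes without a read as a term, and the one without both the 22-h and the 28-h library, were chosen after seeing the data. No feature named by the rule changed direction under any alternative run on it. Of the 19 list calls, GABA signalling and meninges did, both with the oligodendrocyte term, and genes named outside the rule and the other lists were not checked for direction. Of the 17 rhythmic genes, DESeq2, DESeq2 size factors in edgeR, no filter, a mean of at least 50 reads, the 12-h term and the number of genes without a read as a term each called all 17. No scaling and the replicate block called 16 of them, the linear trend 15, the oligodendrocyte term 14, and the fit without both the 22-h and the 28-h library 13. Of 125 named genes, introns, junctions and exons, 28 passed. DESeq2 size factors in edgeR moved no count by over 1.5 times.

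Without a filter the counts were 362 for the 24-h rhythm, 150 for day-night, 243 for dusk-dawn, 164 for the 12-h term, 2 for the cycle, 3 for antisense, 202 for introns and 238 for junctions. Of the 362 genes 1 lay below the filter used here, so the rise came from genes tested both ways, and its cause was not tested. DESeq2 called 98, 56, 34 and 8 genes for the first 4 of these, 87 introns and 27 junctions, and the cause was not tested. Of 117 named features tested by DESeq2, 97 stayed on their side of the threshold, 18 rose past it (Cirbp and Rora among them) and 2 fell below it (Pmch and Chchd2 junctions).

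With the 12-h contrast as a term, 27 genes were rhythmic and 28 differed between day and night, and 0 junctions passed by edgeR (4145 at an unadjusted p under 0.05, DESeq2 not run with this term). Ion channels were lost (0.0536), and Cirbp passed for the 24-h rhythm (0.0348). With the oligodendrocyte term 34 genes differed between day and night, 1 between cycles, and 22 introns and 50 junctions passed, while GABA signalling (0.583) and meninges (0.0141) changed direction. Oxidative phosphorylation (0.0520), ion channels (0.728), oligodendrocyte markers (0.728), microglia (0.586) and glucocorticoid-responsive genes (0.443) were lost with that term. The oligodendrocyte list is the term itself, which is why it was lost. For the other changes the cause was not tested.

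The linear trend gave 5 genes for dusk-dawn, 2 for the 12-h term, 2 for the cycle, 22 introns and 3 junctions. Without both the 22-h and the 28-h library there were 7 dusk-dawn genes, 1 12-h gene and 15 introns, and by edgeR 0 junctions (3892 at an unadjusted p under 0.05) and 0 exon usage genes for day-night (106), with DESeq2 not run. TMM on the features themselves gave 1 antisense gene and 7 junctions, no scaling 9 junctions, and a mean of at least 50 reads 4 junctions. The gene-level F test gave 18 exon usage genes for dusk-dawn. With an estimated correlation 0 of 60 list tests passed by camera, while 19 passed with no scaling, 19 with the replicate block and 15 to 22 without 1 library. The cause was not tested.

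The replicate block enters the cycle as a term, and its numbers do not pair samples. With the block 6 dusk-dawn genes passed, and by edgeR 0 junctions (3522 at an unadjusted p under 0.05) and 0 exon usage genes for day-night (305), with DESeq2 not run with the block. Of 125 named features 114 stayed on their side of the threshold with the block, 9 fell below it and 2 rose past it, Rora (0.0305) among them. The cycle term itself, with 0 genes by edgeR and DESeq2 and 543 at an unadjusted p under 0.05, serves as its check.

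Each fit without 1 library left 1 library at that time, which was assumed to vary like the others. The ranges were 7 (CT10 replicate 2) to 43 (CT16 replicate 1) rhythmic genes, 4 (CT10 replicate 2) to 28 (CT22 replicate 2) for day-night, 3 to 60 (CT16 replicate 1) for dusk-dawn, 0 to 33 (CT4 replicate 2) for the 12-h term, 0 to 2 (CT16 replicate 1) for the cycle and 0 to 1 (CT4 replicate 2) for antisense. Introns ranged from 2 (CT4 replicate 2) to 51 (CT16 replicate 1), junctions from 0 (CT22 replicate 1) to 62 (CT16 replicate 1), exon usage for day-night from 0 to 70 (CT16 replicate 1) and core clock members from 3 (CT10 replicate 2) to 7 (CT22 replicate 1). The median peak of introns relative to genes ran from -0.837 to -0.435 h. It was computed anew over the genes that passed both tests in each fit, so the genes differed between fits. For antisense genes and junctions 0% of simulated 2-fold rhythms were recovered, and the part of depth in this was not tested.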

Other observations

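Tests chosen only after the result was seen were those of introns with 1 or 2 reads, of wrong-strand reads, of both explanations of the oligodendrocyte score, of a daily temperature cycle, and the relabelings of core clock members and with the oligodendrocyte score as a term. The circadian times of the libraries were exchanged at random, and the real assignment is 1 of those counted. For introns 1 of 100 relabelings, the real one, gave as many calls (36, highest other 13). This is the lowest share that 100 relabelings can give. Chance was thus unlikely for the count of introns, but single introns were not tested this way. In the relabelings chosen after the result was seen, 2 of 100 gave as many core clock members (5, highest other 5) and 4 of 100 as many genes with the oligodendrocyte score as a term (19, highest other 89). The latter does not exclude chance for the 17 genes called without that term.

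Chance was not made unlikely for 6 results. As many calls came from 6 of 100 relabelings for rhythmic genes (17, highest other 71), 6 for day-night (16 and 55), 9 for dusk-dawn (3 and 85) and 50 for gene lists (19 and 27). The same held for 13 of 40 for junctions (14 and 165) and 9 of 30 for exon usage by day and night (3 and 122). A count of 0 is matched by every relabeling by construction, so nothing about chance follows for the remaining results: 100 of 100 for the 12-h term (highest other 63), 100 for the cycle (82) and 100 for antisense (2), and 30 of 30 for exon usage at dusk and dawn (131). The relabelings with the most calls per axis (85 and 55) both set the 22-h, 34-h, 58-h and 64-h libraries against the rest. Those with many more calls than the real one point to a structure of the samples, and 3 of these 4 libraries had the highest oligodendrocyte scores.

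Markers of tissues next to the SCN stood high in single libraries. CT22 replicate 1 held 1040 reads of the pituitary gene Gh and 244 of Prl, and Prl had an adjusted p of 0.0617 for the 24-h rhythm by edgeR. CT4 replicate 1 held 1176 reads of Ttr and 1154 of Pmch. CT10 replicate 1 held 582 reads of Pomc, 193 of Npy and 173 of Nr5a1. CT22 replicate 1 had 79 junctions with at least 50 reads and at least 5 times those of every other library, against 2 in CT4 replicate 1, 2 in CT10 replicate 1 and 0 in each other library. Libraries of the same circadian time differed by a chi-square per gene of 7.30 to 12.6, and the lowest value of all pairs was 6.92, so no library was a copy of another. That lowest pair was CT16 replicate 1 and CT22 replicate 2, while both CT16 libraries differed by 12.6. Libraries of the same time were thus not always the most alike.

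The number of genes without a read alternated: 3154 to 3674 in the libraries at CT4 and CT16 against 2589 to 3121 at CT10 and CT22. A set of genes switched off at CT4 and CT16 would share its absences among those libraries. The log2 odds ratio of shared absence was 0.08 ± 0.24 (SD, 6 pairs among 4 libraries) there and 0.62 ± 0.25 at CT10 and CT22. Over these 1581 genes with few reads the difference was -0.54, so no excess of shared absence was seen. Unshared absences in the same libraries would also lower the ratio, so such a set is not excluded. Fewer distinct molecules behind the reads could not be told apart from other causes: introns with 1 read over introns with 2 reads stood at 1.15 ± 0.0720 (SD, n = 4) at CT4 and CT16 and 1.33 ± 0.114 at CT10 and CT22, with an exact permutation p of 0.0857 from 4 against 4 libraries.

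In CT10 replicate 1, antisense reads of genes with at least 5000 sense reads were 0.254 of the median of the other libraries (0.864 to 1.2 in these), and 1.87 times it for genes with under 10 sense reads. Less RNA of the abundant genes is argued against by their sense reads, at 0.997 of the median. A candidate explanation is fewer sense reads counted on the wrong strand, with totals made equal afterwards. Its test used the counts in which the drop was seen, and other technical or biological differences of that library were not tested.

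The oligodendrocyte score, higher at dusk, differed within circadian times by 0.73 at CT4, 0.27 at CT10, 0.89 at CT16 and 0.08 at CT22, against a range of 1.09 between the means of the times. More myelinated tissue in some dissected pieces and a 24-h rhythm of these genes cannot be told apart with 2 libraries per time. The first needs all markers to move together, and correlations with the mean of the others were at least 0.808 for 11 markers but 0.352 for Opalin. The second needs both libraries of a time to match, and their largest difference was 0.810 of the range between times.

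A daily temperature cycle of the tissue may lower heat shock genes and raise cold-inducible genes by day: all 19 heat shock members were lower by day and 2 of 3 cold-inducible genes higher, but the list calls were lost with an estimated correlation (0.132 and 0.264), so the test does not decide.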
